A study of Mus musculus with 12 samples.

How the data were processed

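RNA was measured in 12 libraries of mouse embryonic fibroblasts, 3 in each of 4 groups that cross 2 genotype labels (wildtype, RBBP5 KO) with 2 media (full medium, EBSS). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, poly(A) RNA was prepared from column-purified, DNase-treated RNA with an Illumina TruSeq kit. Values were deposited by the authors as TPM per gene symbol in one table for all libraries. Salmon and the mm10 build are named in the submitters' processing notes. The Salmon version, the transcript annotation and the way transcripts were summed to genes are not given in the sources used here. Each column summed to 92.3% to 99.4% of 1e+06 TPM over the symbols used. TPM keeps no count or depth, so no counting interval is given and no count model was run. Read depth therefore limits low genes to an unknown extent.

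Of 25117 symbols, 4859 were at 0 in all 12 libraries, and 12653 with a TPM of at least 1 in at least 3 libraries were tested. Values were transformed to log2(TPM + 1). One linear model with a mean for each of the 4 groups was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3), with moderated variances and a trend of variance on mean expression. The 4 pairwise comparisons and the genotype by medium interaction were taken from this fit. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the genes of a comparison, with 0.05 as the threshold. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

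Gene coordinates and transcript lengths are from GENCODE vM21 on GRCm38, the assembly that mm10 names. Of the 12653 tested symbols, 12413 (98.1%) matched it. The annotation behind the deposited table may differ from it.

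There were 38 gene lists, fixed before the data were examined, and 37 were tested. The list of mRNAs encoded by mitochondrial DNA had 0 members among the symbols used here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists of a comparison. Camera compares a list with all other genes, so list medians are given relative to the median of all genes. Camera with an estimated correlation and fry were run beside it. Member counts come from the test over all genes and from adjustment over the list alone. In full medium all 37 lists are reported. In the other comparisons the lists described were picked from those that passed, or that passed in another comparison, after their values were seen.

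Genes to name were chosen by a rule written before the data were examined. It takes Rbbp5, the 8 largest rises and 8 largest falls per comparison among called genes with a mean TPM of at least 5 in the higher group and no overlap between the 3 libraries of each group, and up to 4 called members of each list described, or 2 where none was called. The overlap condition did not apply to the interaction. Predicted genes, pseudogenes and ribosomal protein genes were left out of the largest rises and falls. Some genes that meet the rule are not reported here. The genes named for the comparisons of groups that differ in both genotype and medium, and those of a single library, were chosen after their values were seen, as were Lyz2 and Hspa5 per library. With 3 libraries against 3, chance alone separates the groups completely for 10% of genes.

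The procedure was tested on simulated data drawn without group differences from each gene's mean over all libraries and its spread within groups, with 200 of 12653 genes then changed. At a log2 change of 1, it recovered 75% of the changed genes for KO against wildtype in full medium and 78% in EBSS, 75% and 78% for EBSS in labelled wildtype and labelled KO, and 50% for the interaction. At a log2 change of 2, it recovered 92%, 92%, 97%, 94% and 86%. Of its calls, 2.34%, 7.1%, 4.44%, 4.97% and 5.56% were false. In a simulation of the lists, camera called the 1 shifted list and 0 of the others. Genes were drawn independently of each other, so this cannot tell how camera does where the members of a list are correlated. Neither simulation held a shift of most genes, so the false calls above do not carry over to comparisons with one.

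Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean TPM of at least 5, and 3 other scalings. These were median-of-ratios scaling, quantile normalization, and ribosomal protein genes left out with the rest rescaled. Further alternatives were fits on the 6 libraries of a comparison, robust variances, no variance trend, library weights, a 2-fold minimum, the replicate number as a block, and each library left out in turn. The comparisons of groups that differ in both factors, the interaction with the EBSS genotype labels exchanged, and the fits without pairs of libraries that stood apart, were added after seeing the data. Raw reads were not analysed here.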

Results

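Polyadenylated RNA was sequenced from mouse embryonic fibroblasts (MEFs) that carry floxed alleles of Rbbp5 and a Cre recombinase at the Rosa26 locus. RBBP5 is a core subunit of the SET1/COMPASS and MLL complexes, which methylate histone H3 at lysine 4. Tamoxifen for 7 days gave the cells labelled KO, and cells without it were labelled wildtype. Each was then kept for 16 hours in full medium (DMEM with serum) or in Earle's balanced salt solution (EBSS), a glucose-containing salt solution without amino acids or serum that is used to starve cells. The 4 groups had 3 libraries each, 12 in all. Values were TPM, a relative abundance corrected for transcript length, for 25117 gene symbols, of which 4859 were at 0 in all 12 libraries and 12653 were tested. The sequencing depth of each library is unknown, because TPM keeps none. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Each p below comes from limma and is adjusted by the Benjamini-Hochberg method.

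Rbbp5, the targeted gene (ENSMUSG00000026439.14, chromosome 1 from 132477365 to 132505659 on GRCm38), did not follow the genotype labels in EBSS. In wildtype libraries in full medium it was at 26.2, 25.7 and 26.2 TPM, and in KO libraries in full medium at 7.47, 9.34 and 8.31 TPM. In the libraries labelled KO, EBSS it was at 31.9, 24.6 and 23 TPM, the wildtype level. In the libraries labelled wildtype, EBSS it was at 12.4, 14 and 11.8 TPM. KO against wildtype therefore gave a log2 change of −1.53 (SE 0.13, adjusted p = 3.4e-06) in full medium. Labelled KO against labelled wildtype in EBSS gave 0.99 (SE 0.13, adjusted p = 3.2e-05). The high level in labelled KO, EBSS held with median-of-ratios scaling, at 1.40 against KO in full medium (adjusted p = 3.7e-06). The difference between the 2 EBSS groups did not, at 0.07 (adjusted p = 0.59). The deleted exons are not given in the sources used here, and gene-level TPM can keep reads of exons that were not deleted. Because of these values, both EBSS groups are named below by their labels, and every direction drawn between them rests on labels in doubt. Rbbp5 went against the KO label in EBSS with and without median-of-ratios scaling. It went against the wildtype label in EBSS as deposited but not with that scaling, at −0.02 against wildtype in full medium (limma adjusted p = 0.88).

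**Figure D1:**
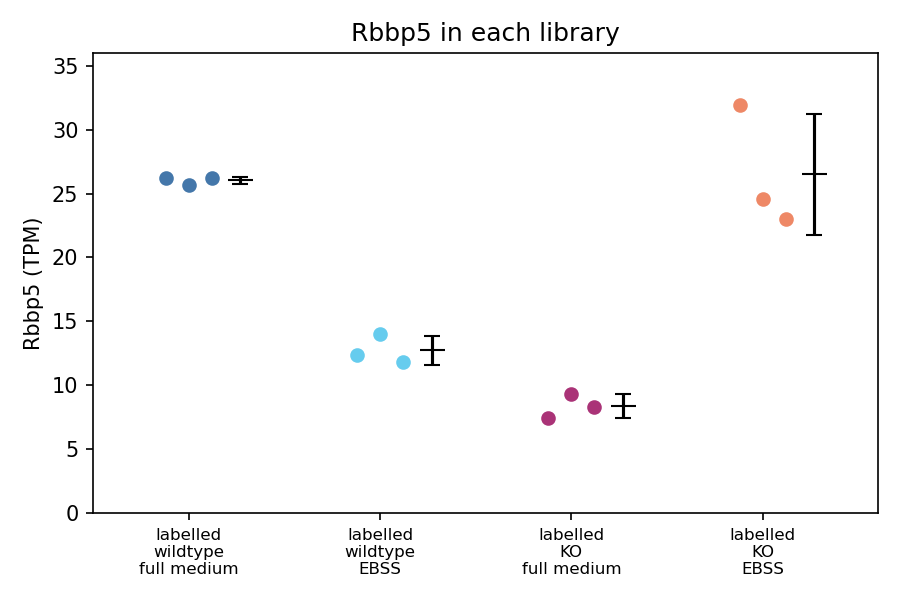
Rbbp5 in TPM (vertical axis) in each of the 12 libraries (points), grouped by label, with the mean and SD of each group (n = 3) as a bar at the right of its points. The libraries labelled KO, EBSS lie between 23 and 31.9 TPM, and those labelled wildtype, EBSS between 11.8 and 14 TPM.

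The 3 libraries labelled wildtype, EBSS stood apart from the other 9. Cytosolic ribosomal protein genes took 31.2% to 33.6% of their TPM, against 14.4% to 18.1% elsewhere. Rn45s, the ribosomal RNA precursor, was at 1450, 2100 and 1610 TPM, against 68.3 to 272 TPM elsewhere. The median tested gene was at 10.1 to 10.5 TPM, against 17.5 to 23 TPM. Replicate 3 of this group listed 1122 tested genes at 0, and the other 11 libraries listed 12 to 229. Its log values correlated at 0.942 and 0.941 with replicates 1 and 2, which correlated at 0.99 with each other. It was at least 2-fold from them at 1739 and 1815 genes, while replicates 1 and 2 were so at 127. The first principal component of all libraries held 62% of the variance and the second 24.1%. Correlations of log values across genes, which are not independent replicates, ranged from 0.968 to 0.994 between wildtype, full medium and labelled KO, EBSS. They ranged from 0.91 to 0.918 between wildtype and KO in full medium, and from 0.849 to 0.884 between wildtype, full medium and labelled wildtype, EBSS. Between KO, full medium and labelled wildtype, EBSS they ranged from 0.861 to 0.902.

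The first comparison asks what differed in fed cells, KO against wildtype in full medium. Only the cells labelled KO had tamoxifen, so effects of tamoxifen or of Cre cannot be told apart from loss of RBBP5 in any comparison of genotypes. KO cells had much less RNA for extracellular matrix, interferon-stimulated and inflammatory genes, and more for subunits of the respiratory chain. Col3a1, a fibrillar collagen (chromosome 1 from 45311538 to 45349706), was at 606 ± 17.3 TPM in wildtype and 41.1 ± 10.8 TPM in KO (mean ± SD, n = 3 each). Gbp2, an interferon-induced GTPase, was at 39.1 ± 1.42 and 2.62 ± 0.372 TPM. Cxcl1, a neutrophil chemokine, was at 163 ± 5.08 and 4.53 ± 0.639 TPM. Ndufb10, a complex I subunit, was at 214 ± 8.67 TPM in wildtype and 681 ± 62 TPM in KO.

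The largest falls were in Crabp1, a retinoic acid binding protein (chromosome 9 from 54764748 to 54773110; −6.87, adjusted p = 5.1e-10), and in the imprinted noncoding RNA H19 (chromosome 7 from 142575529 to 142578143; −6.67, adjusted p = 1.5e-08). Igfbp3, which binds insulin-like growth factors (chromosome 11 from 7206086 to 7213923), fell by 6.12 (adjusted p = 3.6e-08). Has2, a hyaluronan synthase, was at −5.69, the gap junction gene Gjb2 at −5.22, and the serine protease inhibitor Serpina3g and the collagen Col5a3 both at −4.87. Acta1, skeletal muscle actin, rose by 4.91 (adjusted p = 4.9e-07), Prl2c3, of the prolactin family, by 4.28, the cadherin Cdh17 by 3.97, Aldh1a7 by 3.78 and S100a7a by 3.47.

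Of 58 extracellular matrix genes, 1 rose, 48 fell and 9 did not pass the test, with the same 1 and 48 adjusted over the list alone and 0 and 45 with median-of-ratios scaling. Col6a3 was at −3.96 and Tnc, tenascin C, at −3.48, and the list's median was −1.53 relative to all genes (camera adjusted p = 2.9e-11; adjusted p = 0.73 with an estimated correlation). Of 43 interferon-stimulated genes, 0 rose, 38 fell and 5 did not pass, 0 and 38 adjusted over the list alone and 1 and 36 with that scaling. Oasl2 was at −3.49, Rtp4 at −3.16 and Gbp3 at −3.02, with a relative median of −1.73 (camera adjusted p = 3.5e-09; adjusted p = 0.73 with an estimated correlation). Of 36 NF-kB, cytokine and secretory-phenotype genes, 0 rose, 27 fell and 9 did not pass, 0 and 27 adjusted over the list alone and 0 and 26 with that scaling. Il1rl1, the interleukin 33 receptor, was at −4.45 and Lif at −3.55, with a relative median of −1.55 (camera adjusted p = 2.5e-06; adjusted p = 0.074 with an estimated correlation). Of 30 serum-responsive and immediate early genes, 5 rose, 20 fell and 5 did not pass, 5 and 21 adjusted over the list alone and 6 and 20 with that scaling. The transcription factors Egr1, Egr2 and Egr3 were at −3.44, −2.86 and −2.76, with a relative median of −0.99 (camera adjusted p = 0.041; adjusted p = 0.95 with an estimated correlation). That call was lost without any one of replicates 1, 2 and 3 of labelled wildtype, EBSS (adjusted p = 0.052, 0.064 and 0.11) or replicates 2 and 3 of KO, full medium (adjusted p = 0.058 and 0.072).

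Of 76 nuclear-encoded oxidative phosphorylation subunits, 56 rose, 5 fell and 15 did not pass, with the same 56 and 5 adjusted over the list alone and 58 and 2 with median-of-ratios scaling. Ndufv3 rose by 1.84, Ndufb10 by 1.66 and Cox6a1, of complex IV, by 1.46, with a median of 0.70 relative to all genes (camera adjusted p = 1.3e-13; adjusted p = 0.11 with an estimated correlation). Of 70 lysosomal genes, 33 rose, 15 fell and 22 did not pass, 34 and 17 adjusted over the list alone and 38 and 13 with that scaling. The sialidase Neu1 rose by 1.54 and the cathepsin Ctsh fell by 3.04, with a relative median of 0.41 (camera adjusted p = 0.0013; adjusted p = 0.48 with an estimated correlation). Of 40 subunits of the 26S proteasome, 18 rose, 5 fell and 17 did not pass, 18 and 5 adjusted over the list alone and 25 and 1 with that scaling. Psmb6 rose by 0.89 and Adrm1 by 0.73, with a relative median of 0.34 (camera adjusted p = 0.0025; adjusted p = 0.11 with an estimated correlation). Of 76 cytosolic ribosomal protein genes, 31 rose, 15 fell and 30 did not pass, 32 and 15 adjusted over the list alone and 40 and 7 with that scaling. Rps15 rose by 1.07 and Rpl10 fell by 1.38, with a relative median of 0.35 (camera adjusted p = 0.0025; adjusted p = 0.95 with an estimated correlation). Ribosomal protein genes share reads with many pseudogenes, so single members are uncertain. Quantile normalization ended the calls of the ribosomal protein list (adjusted p = 0.62) and of the proteasome list (adjusted p = 0.14).

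The other 29 lists did not pass camera, with adjusted p from 0.066 to 0.9, and in 3 of them camera's direction was opposite to the list's relative median (ER folding at 0.02, glycolysis at 0.01 and DNA replication at −0.03). Of their 855 entries, 163 rose, 282 fell and 410 did not pass, and 157 rose and 272 fell when adjusted over the list alone, but 227 rose and 203 fell with median-of-ratios scaling. The balance of falls over rises given below ended or turned with that scaling for ER folding (4 and 4), chaperones (16 higher and 10 lower), DNA replication (14 and 11), mitosis (12 and 4), fatty acid oxidation (10 and 8), glycolysis (10 and 10), NRF2 (12 and 8) and neural markers (3 and 2). Even counts turned to more rises for p53 targets (10 and 4) and cholesterol (6 and 4). Among the 20 other subunits of SET1/COMPASS and MLL complexes, 4 rose and 8 fell. Dpy30 rose by 1.25, while Hcfc1 was at −1.25, the methyltransferase Kmt2a at −0.91 and Wdr82 at −0.88. Of 33 endoplasmic reticulum (ER) chaperones and folding enzymes, 2 rose and 6 fell. Of 34 genes of the unfolded protein response and ER-associated degradation, 4 rose and 3 fell. In ER translocation and ER-Golgi transport, 10 of 66 rose and 31 fell, and this list passed with quantile normalization (adjusted p = 0.009). Of 38 targets of ATF4, the transcription factor of the integrated stress response, 1 rose and 7 fell. The spread in this fit is shared by all 12 libraries. It includes replicate 1 of labelled KO, EBSS, where this list's median was 1.62 against wildtype in full medium (0.00 and −0.1 in replicates 2 and 3). Members that did not pass may have been missed for that reason. Of 20 cytosolic tRNA synthetases, 3 rose and 2 fell, and this list passed without replicate 1 of labelled KO, EBSS (adjusted p = 0.021). Of 51 autophagy genes, 20 rose and 13 fell, and this list passed without replicate 1 or 2 of KO, full medium or replicate 1 of labelled KO, EBSS (adjusted p = 0.039, 0.045 and 0.048) and with median-of-ratios scaling (adjusted p = 0.024). Of 41 cytosolic and mitochondrial chaperones, 11 rose and 14 fell. Of 48 ribosome biogenesis genes, 12 rose and 11 fell, and of 62 splicing genes, 11 rose and 31 fell, a list that passed with quantile normalization (adjusted p = 0.032). Of 50 DNA replication genes, 9 rose and 19 fell. Of 56 mitotic genes, 7 rose and 11 fell over all genes, and 3 rose and 5 fell adjusted over the list alone. Of 33 p53 targets, 10 rose and 10 fell.

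Among metabolic lists, 6 of 26 cholesterol genes rose and 6 fell, and 2 of 21 fatty acid synthesis genes rose and 11 fell. In fatty acid oxidation, 10 of 34 rose and 11 fell, and in glycolysis and hypoxia, 6 of 32 rose and 13 fell. Of 34 NRF2 and antioxidant genes, 7 rose and 9 fell. Of 35 actin cytoskeleton genes, 4 rose and 17 fell. Of 19 circadian clock genes, 1 rose and 10 fell. Of 26 FoxO and growth-factor-withdrawal genes, 4 rose and 11 fell, and of 19 Hox genes, 2 rose and 6 fell. Among markers of other cell types, 2 of 6 macrophage genes rose and 1 fell, and 2 of 7 endothelial genes rose and 5 fell. Of 9 epithelial markers, 5 rose and 1 fell, and of 11 skeletal muscle markers, 4 rose and 4 fell. Of 7 neural markers, 1 rose and 2 fell, of 9 adipocyte markers, 1 rose and 5 fell, and of 8 cartilage and bone markers, 2 rose and 4 fell.

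**Figure D2:**
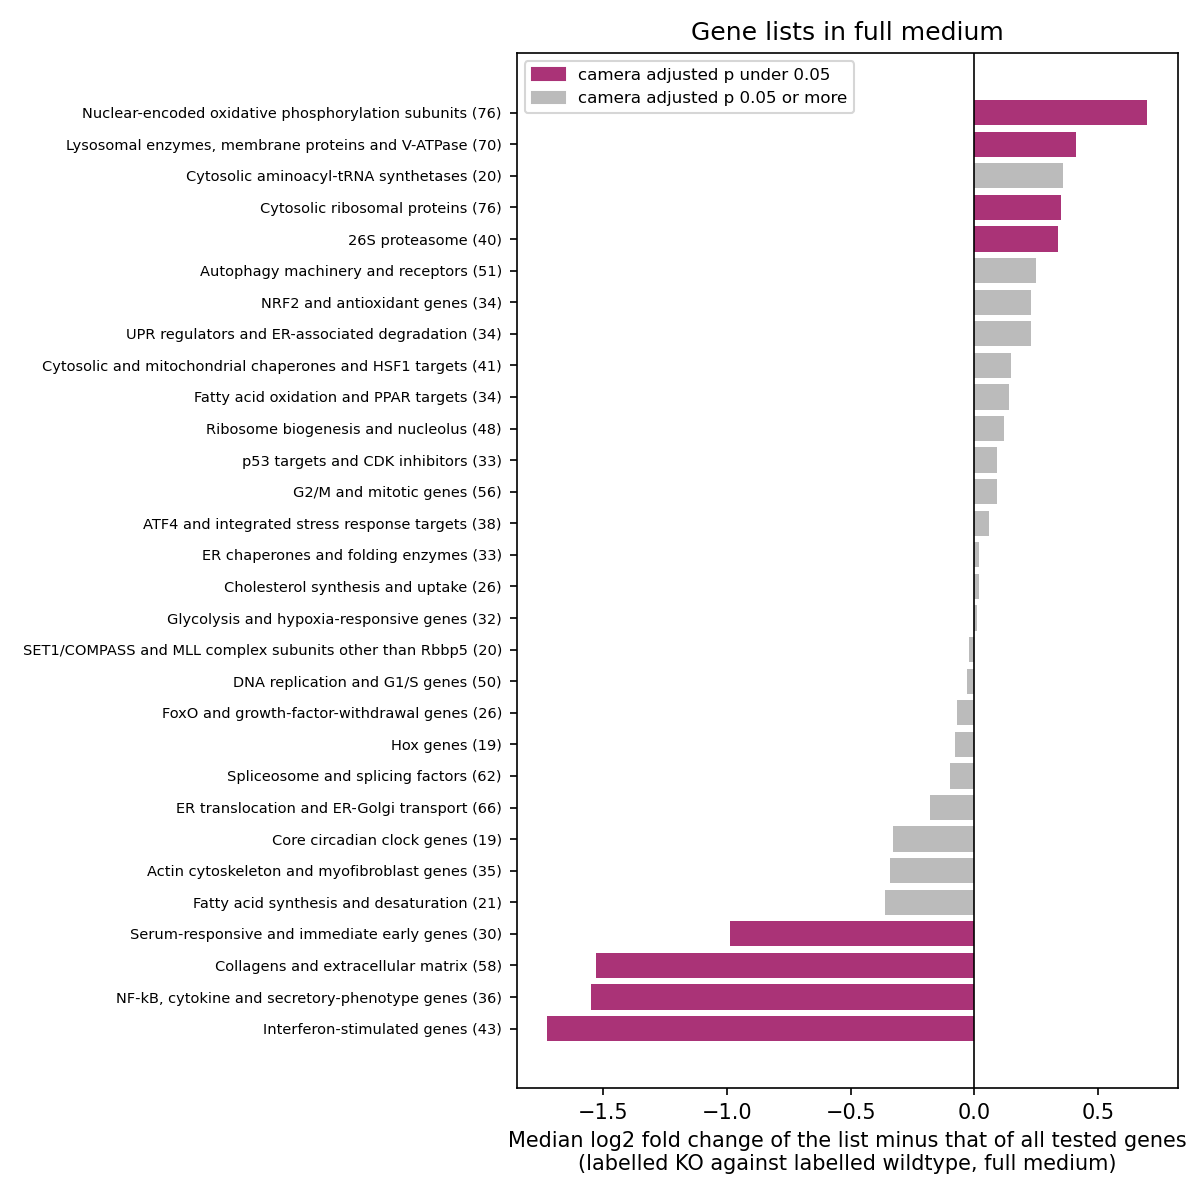
Median log2 fold change of each gene list minus the median of all tested genes (horizontal axis), KO against wildtype in full medium, for the lists other than cell type markers, with the number of tested members in brackets. Bars are coloured by whether camera with a preset correlation passed; the interferon list is lowest at −1.73 and the oxidative phosphorylation list highest at 0.70.

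Over all 12653 genes, 7078 (55.9%) passed limma's adjusted p of 0.05, 2545 higher and 4533 lower in KO. The median change of all genes was −0.17, and median-of-ratios scaling, which removes that shift, called 6791 genes, 3374 higher and 3417 lower. At 2-fold or more, 707 were higher and 1835 lower. Lower genes were on average longer (Spearman's rho of change with transcript length −0.18 across genes).

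The second comparison asks the same question in EBSS, labelled KO against labelled wildtype, and its directions ran opposite to those in full medium for many genes. Matrix and interferon-stimulated genes were higher in the libraries labelled KO, and ribosomal protein genes were lower. Col3a1 was at 561 ± 210 TPM in labelled KO and 23.3 ± 0.682 TPM in labelled wildtype (mean ± SD, n = 3 each). Usp18, an interferon-induced protease (chromosome 6 from 121245906 to 121270917), was at 45 ± 11.7 and 0.467 ± 0.314 TPM. Rps12 was at 4390 ± 135 TPM in labelled KO and 14600 ± 1450 TPM in labelled wildtype. H19 was higher by 7.05 (SE 0.24, adjusted p = 4e-09), Igfbp3 by 6.11, the proteoglycan decorin (Dcn) by 6.03, Crabp1 by 5.75 and Tnc by 5.43.

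Rpph1, the RNA of ribonuclease P (chromosome 14 from 50807449 to 50807767), was lower by the largest amount, at −6.61 (adjusted p = 8.6e-10). Rmrp, the RNA of the related ribonuclease MRP, was at −6.04, and the repeated small RNA Rn4.5s at −5.19. These RNAs are not polyadenylated, so their levels in poly(A) libraries also depend on how well the selection worked. They move with the group labelled wildtype, EBSS, where Rn45s is also high.

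Of 76 ribosomal protein genes, 0 were higher, 75 lower and 1 did not pass, the same adjusted over the list alone, and 0 and 76 with median-of-ratios scaling. Rpl41 was at −1.60, and the list's median was −1.95 relative to all genes (camera adjusted p = 7.8e-76; adjusted p = 0.0032 with an estimated correlation). Of 43 interferon-stimulated genes, 43 were higher and 0 lower, also over the list alone, and 39 and 0 with that scaling. Rtp4 was higher by 4.45, with a relative median of 1.89 (camera adjusted p = 3.1e-05; adjusted p = 0.49 with an estimated correlation). Of 58 matrix genes, 57 were higher and 0 lower, 57 and 1 adjusted over the list alone and 45 and 1 with that scaling, with a relative median of 1.06 (camera adjusted p = 2.3e-05; adjusted p = 0.49 with an estimated correlation). Of 66 genes of ER translocation and ER-Golgi transport, 63 were higher and 0 lower, also over the list alone, and 35 and 11 with that scaling. Creb3l1, an ER-membrane transcription factor of the secretory pathway, was higher by 3.50 and the signal peptidase subunit Spcs3 by 2.82, with a relative median of 0.41 (camera adjusted p = 3.6e-05; adjusted p = 0.49 with an estimated correlation). Of 26 cholesterol synthesis and uptake genes, 24 were higher and 0 lower, 25 and 0 adjusted over the list alone and 18 and 3 with that scaling. Cyp51 was higher by 3.04, with a relative median of 1.01 (camera adjusted p = 0.01; adjusted p = 0.49 with an estimated correlation). Of 56 mitotic genes, 55 were higher and 0 lower, also over the list alone, and 21 and 6 with that scaling, which ended the list's call (adjusted p = 0.07). The kinases Ttk and Plk1 were higher by 2.98 and 2.97, with a relative median of 0.31 (camera adjusted p = 0.0044; adjusted p = 0.68 with an estimated correlation).

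In some lists the balance of higher and lower members depended on the scaling. Of 70 lysosomal genes, 39 were higher and 21 lower as deposited, also over the list alone, but 10 and 43 with median-of-ratios scaling. Sgsh and Ids, enzymes of glycosaminoglycan breakdown, were higher by 2.53 and 2.46, while the list's median was −0.51 relative to all genes (camera adjusted p = 0.0011; adjusted p = 0.32 with an estimated correlation). Of 51 autophagy genes, 30 were higher and 12 lower, also over the list alone, but 12 and 32 with that scaling, with a relative median of −0.41 (camera adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation). Of 40 proteasome subunits, 37 were higher and 0 lower, also over the list alone, but 8 and 18 with that scaling. The proteasome list's relative median was −0.10 although camera, which weighs the test statistics, gave higher (adjusted p = 0.026; adjusted p = 0.32 with an estimated correlation). That call was lost without replicate 3 of labelled wildtype, EBSS (adjusted p = 0.088). Of 30 immediate early genes, 12 were higher and 12 lower, also over the list alone, but 5 and 17 with that scaling. Fos was at −2.72 and the phosphatase Dusp4 at −2.76, while Fosl2 was higher by 2.49, with a relative median of −0.92 (camera adjusted p = 1.1e-05; adjusted p = 0.32 with an estimated correlation).

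Over all genes, 10182 (80.5%) passed limma's adjusted p of 0.05, 9097 higher and 1085 lower in the libraries labelled KO. The median change of all genes was 0.91, and median-of-ratios scaling called 8071, 4377 higher and 3694 lower. At 2-fold or more, 5733 were higher and 453 lower. The comparisons in full medium and in EBSS share no library. With that scaling, 2012 genes were lower in KO in full medium and higher in labelled KO in EBSS, where independent lists give 1182. Another 1667 were higher and then lower, where independent lists give 985. Lower in both were 552 (998 for independent lists) and higher in both 491 (1167). Camera passed 18 of 37 lists, and 1, the ribosomal proteins, with an estimated correlation.

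The third comparison asks what EBSS changed in wildtype, the libraries labelled wildtype, EBSS against wildtype in full medium. Ribosomal protein genes and several small structural RNAs were higher, and matrix, interferon, cholesterol and mitotic genes were lower. Rpl41 was at 4680 ± 431 TPM in full medium and 14900 ± 1600 TPM in labelled EBSS (mean ± SD, n = 3 each). Ppp1r15a, a stress-induced phosphatase subunit that is a target of ATF4, was at 73.7 ± 3.19 and 634 ± 7.64 TPM. Rbbp5 itself was at −0.98 (SE 0.13, adjusted p = 3.3e-05) as deposited and at −0.02 with median-of-ratios scaling (adjusted p = 0.88). H19 was at −6.60, Dcn at −6.15, Igfbp3 at −6.09 and Tnc at −5.66.

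Rpph1 rose by 8.25 (SE 0.17, adjusted p = 1.9e-10), Rmrp (chromosome 4 from 43492783 to 43493063) by 7.55, Rn4.5s by 5.66 and Rn45s by 4.61. None of these 4 is polyadenylated. Of 76 ribosomal protein genes, 75 rose, 0 fell and 1 did not pass, also over the list alone, and 76 and 0 with median-of-ratios scaling. Rps15 rose by 1.72, and the list's median was 1.88 relative to all genes (camera adjusted p = 1.9e-70; adjusted p = 0.0042 with an estimated correlation).

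Of 58 matrix genes, 1 rose and 57 fell, also over the list alone, and 1 and 47 with median-of-ratios scaling, with a relative median of −1.32 (camera adjusted p = 1.2e-05; adjusted p = 0.51 with an estimated correlation). Of 43 interferon-stimulated genes, 0 rose and 42 fell, also over the list alone, and 0 and 39 with that scaling. Usp18 fell by 5.29, with a relative median of −1.79 (camera adjusted p = 6.8e-05; adjusted p = 0.51 with an estimated correlation). Of 26 cholesterol genes, 0 rose and 25 fell, also over the list alone, and 3 and 17 with that scaling. Cyp51 was at −3.05, with a relative median of −1.07 (camera adjusted p = 0.0093; adjusted p = 0.51 with an estimated correlation). Of 56 mitotic genes, 0 rose and 56 fell, also over the list alone, and 5 and 37 with that scaling. Ttk was at −3.24 and Plk1 at −2.93, with a relative median of −0.57 (camera adjusted p = 0.00039; adjusted p = 0.54 with an estimated correlation). Of 66 genes of ER translocation and ER-Golgi transport, 0 rose and 64 fell, also over the list alone, and 13 and 34 with that scaling, with a relative median of −0.36 (camera adjusted p = 2e-04; adjusted p = 0.51 with an estimated correlation).

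Member counts of the stress and degradation lists also depended on the scaling. Of 38 ATF4 targets, 12 rose and 14 fell as deposited, 12 and 13 adjusted over the list alone, but 18 and 4 with median-of-ratios scaling. Ppp1r15a rose by 3.09 and Atf3 by 2.64 while Stc2 fell by 3.63, and the list's median was 0.77 relative to all genes (camera adjusted p = 1.5e-05; adjusted p = 0.54 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.079). Of 51 autophagy genes, 14 rose and 29 fell, also over the list alone, but 31 and 12 with median-of-ratios scaling. Gabarapl1, an autophagosome protein, rose by 2.51 and the mitophagy receptor Bnip3 fell by 2.65, with a relative median of 0.46 (camera adjusted p = 0.0072; adjusted p = 0.51 with an estimated correlation). Of 70 lysosomal genes, 20 rose and 38 fell, also over the list alone, but 45 and 11 with that scaling. The proton pump subunit Atp6v0b rose by 2.29 and Ids fell by 2.74, with a relative median of 0.54 (camera adjusted p = 0.0018; adjusted p = 0.33 with an estimated correlation). Of 40 proteasome subunits, 0 rose and 36 fell, also over the list alone, but 17 and 9 with that scaling. Their median was 0.09 relative to all genes while camera gave lower (adjusted p = 0.016; adjusted p = 0.33 with an estimated correlation). Of 30 immediate early genes, 13 rose and 13 fell, also over the list alone, but 18 and 5 with that scaling. Dusp4 rose by 2.65 and Fos by 2.55, with a relative median of 0.73 (camera adjusted p = 2.3e-05; adjusted p = 0.33 with an estimated correlation).

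Of 6 macrophage markers, 3 rose and 1 fell, also over the list alone, with a median of 1.79 relative to all genes (camera adjusted p = 0.0028; adjusted p = 0.33 with an estimated correlation). The call was lost with median-of-ratios scaling (adjusted p = 0.089), under which 5 rose and 0 fell. Lyz2, lysozyme, was at 2.22, 2.93 and 48.4 TPM in the 3 libraries labelled wildtype, EBSS, against 0.28 to 0.358 TPM in wildtype, full medium, and replicate 3 is the library with 1122 tested genes at 0. Over all genes, 10260 (81.1%) passed limma's adjusted p of 0.05, 1170 higher and 9090 lower. The median change was −0.94, and median-of-ratios scaling called 8364, 3884 higher and 4480 lower. At 2-fold or more, 486 were higher and 5912 lower. Camera passed 19 of 37 lists, and 1, the ribosomal proteins, with an estimated correlation.

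The fourth comparison asks what EBSS changed in KO cells, the libraries labelled KO, EBSS against KO in full medium. Matrix, interferon-stimulated and inflammatory genes were higher, and oxidative phosphorylation genes lower. Col6a3 was at 7.23 ± 0.659 TPM in full medium and 129 ± 17.7 TPM in labelled EBSS, close to the 127 ± 3.74 TPM of wildtype in full medium (mean ± SD, n = 3 each). Cdh17 was at 70.3 ± 2.18 TPM and 3.3 ± 0.569 TPM. Rbbp5 was higher by 1.54 (SE 0.13, adjusted p = 3.5e-06). Crabp1 was higher by 7.26 (adjusted p = 2.8e-10), H19 by 7.12, Igfbp3 by 6.14, Col5a3 by 5.11 and Creb3l1 by 4.82. Acta1 was at −4.47, Prl2c3 at −4.26 and Cdh17 at −4.06.

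Of 76 oxidative phosphorylation subunits, 3 rose and 55 fell, 4 and 56 adjusted over the list alone and 1 and 63 with median-of-ratios scaling. Ndufb10 was at −1.36 and Uqcr11, of complex III, at −1.31, with a median of −0.75 relative to all genes (camera adjusted p = 3.5e-15; adjusted p = 0.078 with an estimated correlation). Of 43 interferon-stimulated genes, 38 rose and 1 fell, 39 and 1 adjusted over the list alone and 36 and 1 with that scaling. Oasl2 rose by 3.57 and Gbp2 by 3.55, with a relative median of 1.70 (camera adjusted p = 6.6e-10; adjusted p = 0.77 with an estimated correlation). Of 58 matrix genes, 44 rose and 1 fell, 44 and 2 adjusted over the list alone and 43 and 1 with that scaling, with a relative median of 1.35 (camera adjusted p = 6.6e-10; adjusted p = 0.79 with an estimated correlation). Of 36 inflammatory genes, 27 rose and 1 fell, 29 and 1 adjusted over the list alone and 26 and 1 with that scaling. Cxcl1 rose by 4.5 and Il1rl1 by 4.10, with a relative median of 1.30 (camera adjusted p = 4.7e-06; adjusted p = 0.074 with an estimated correlation). Of 30 immediate early genes, 19 rose and 6 fell, 20 and 6 adjusted over the list alone and 17 and 6 with that scaling. Egr1 rose by 3.55, with a relative median of 0.92 (camera adjusted p = 0.027; adjusted p = 0.84 with an estimated correlation). That call was lost without replicate 3 of labelled wildtype, EBSS (adjusted p = 0.079) or replicate 3 of KO, full medium (adjusted p = 0.054).

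Of 40 proteasome subunits, 4 rose and 18 fell, also over the list alone, and 1 and 25 with median-of-ratios scaling. Psmb3 was at −0.83 and Psma2 at −0.75, with a relative median of −0.34 (camera adjusted p = 0.00028; adjusted p = 0.074 with an estimated correlation). Of 70 lysosomal genes, 15 rose and 37 fell, 17 and 37 adjusted over the list alone and 12 and 42 with that scaling. Ctsh rose by 3.10 and Neu1 fell by 1.59, with a relative median of −0.46 (camera adjusted p = 0.00076; adjusted p = 0.44 with an estimated correlation). Of 76 ribosomal protein genes, 12 rose and 30 fell, 13 and 30 adjusted over the list alone and 5 and 37 with that scaling. Rpl10 rose by 1.19 and Rps2 fell by 0.95, with a relative median of −0.32 (camera adjusted p = 0.00091; adjusted p = 0.84 with an estimated correlation). Quantile normalization ended the ribosomal protein call (adjusted p = 0.38). Of 56 mitotic genes, 5 rose and 15 fell, 4 and 14 adjusted over the list alone and 3 and 22 with median-of-ratios scaling, with a relative median of −0.34 (camera adjusted p = 0.017; adjusted p = 0.93 with an estimated correlation). The mitotic call was lost without replicate 1 of labelled KO, EBSS (adjusted p = 0.4) and with quantile normalization (adjusted p = 0.12). Of 51 autophagy genes, 15 rose and 17 fell, also over the list alone, and 8 and 25 with median-of-ratios scaling. Gabarapl2 fell by 1.64, and the cargo receptor Sqstm1 rose by 1.02 (SE 0.35, adjusted p = 0.029), a call that was lost without any one of the 3 KO, full medium libraries (adjusted p = 0.071, 0.064 and 0.07) and with median-of-ratios scaling (adjusted p = 0.051). The autophagy list did not pass (camera adjusted p = 0.078) but passed without replicate 1 of labelled KO, EBSS (adjusted p = 0.024) and with median-of-ratios scaling (adjusted p = 0.038).

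Replicate 1 of labelled KO, EBSS stood apart from replicates 2 and 3, with correlations as low as 0.971 within the group. Col3a1 was at 318 TPM in replicate 1 and at 678 and 685 TPM in replicates 2 and 3, and Hspa5, the ER chaperone BiP, at 8020 TPM against 1550 and 1390 TPM. Over all genes, 6861 (54.2%) passed limma's adjusted p of 0.05, 4217 higher and 2644 lower. The median change was 0.13, and median-of-ratios scaling called 6587, 3322 higher and 3265 lower. At 2-fold or more, 1730 were higher and 675 lower. Camera passed 9 of 37 lists, and 0 with an estimated correlation, while fry, which does not compare a list with other genes, passed 22.

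**Figure D3:**
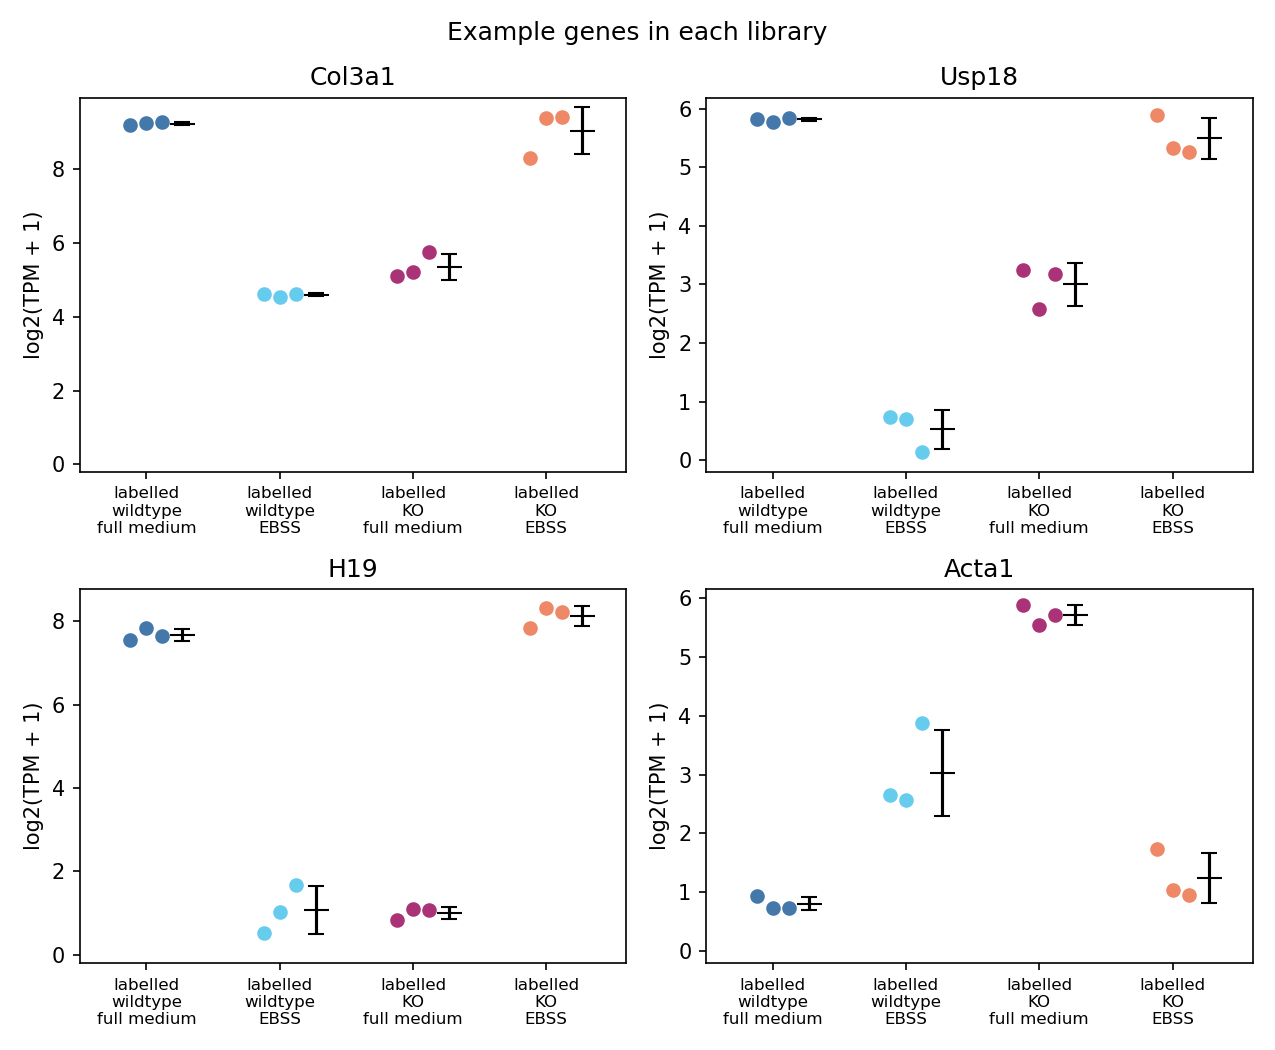
Col3a1, Usp18, H19 and Acta1 on the log2(TPM + 1) scale (vertical axis) in each of the 12 libraries (points), grouped by label, with the mean and SD of each group (n = 3) as a bar at the right of its points. Acta1 is at 45.5 to 58.1 TPM in KO, full medium, at 4.95 to 13.6 TPM in labelled wildtype, EBSS, and at most 2.34 TPM in the other 6 libraries.

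The fifth comparison asks whether the response to EBSS differed between genotypes, labelled KO minus labelled wildtype. Rbbp5 goes against the KO label in EBSS, and as deposited also against the wildtype label. A positive value therefore means only that the labelled response was more positive in KO. H19 differed by 13.73 (SE 0.34, adjusted p = 2.9e-10), Crabp1 by 12.62, Igfbp3 by 12.23, Gjb2 by 9.72, Has2 by 9.71, Serpina3g by 9.48, the kidney androgen-regulated gene Kap by 9.45 and the tubulin Tuba8 by 9.14. Kap was listed at 0 in all KO, full medium and labelled wildtype, EBSS libraries, so its value depends on the pseudocount. So do those of Gjb2, at a mean of 0 TPM in labelled wildtype, EBSS and 0.143 TPM in KO, full medium, and of Serpina3g, at 0.475 and 0.19 TPM. In the same 2 groups H19 was at 1.22 and 1.01 TPM, Igfbp3 at 1.25 and 1.12 TPM and Has2 at 0.819 and 0.306 TPM. Crabp1 was at 0.495 TPM in KO, full medium and Tuba8 at 0.938 TPM in labelled wildtype, EBSS, so the sizes of these 5 depend on the pseudocount too. A comparison with the 2 EBSS genotype labels exchanged was added after seeing the data. In it H19 would be at −0.38 (adjusted p = 0.35), Crabp1 at 1.12 (adjusted p = 0.00065), Igfbp3 at 0.00 (adjusted p = 1), Gjb2 at 0.71 (adjusted p = 0.52), Has2 at 1.68 (adjusted p = 0.17) and Serpina3g at 0.26 (adjusted p = 0.34). These genes were picked for the largest interactions and are low in the same 2 groups. That choice favours small values with exchanged labels, so they do not tell which labels are right. On the negative side were Rpph1 at −6.90, Acta1 at −6.69, Rmrp at −6.41, the cytochrome P450 Cyp2e1 at −6.38 and Rn4.5s at −5.94. The snoRNA host gene Snhg9 was at −5.57 and the small nucleolar RNA Rnu3a at −5.42. In wildtype, full medium and labelled KO, EBSS, Cyp2e1 was at 0.187 and 0.399 TPM, Rnu3a at 0.164 and 0.621 and Acta1 at 0.752 and 1.44. The sizes of these values depend on the pseudocount too. Cyp2e1 also varied between libraries, at 22.3 ± 23.6 TPM in labelled wildtype, EBSS and 11.1 ± 8.92 TPM in KO, full medium (mean ± SD). Rbbp5 differed by 2.52 (SE 0.19, adjusted p = 3.4e-07), and by 1.42 with median-of-ratios scaling (adjusted p = 1.6e-05). With the EBSS labels exchanged, Rpph1 would be at 6.31 (adjusted p = 7e-08), Rmrp at 5.68 (adjusted p = 6.1e-06) and Acta1 at −3.12 (adjusted p = 0.00012), and limma would call 7999 genes, 1134 upward and 6865 downward, but 5971 with median-of-ratios scaling, 2938 upward and 3033 downward.

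Of 43 interferon-stimulated genes, 43 differed upward and 0 downward, also over the list alone, and 41 and 1 with median-of-ratios scaling. Usp18 differed by 7.78, and the list's median was 3.50 relative to all genes (camera adjusted p = 2.4e-07; adjusted p = 0.66 with an estimated correlation). Of 58 matrix genes, 57 differed upward and 0 downward, also over the list alone, and 50 and 2 with that scaling. Col3a1 differed by 8.33, with a relative median of 2.48 (camera adjusted p = 2.9e-08; adjusted p = 0.66 with an estimated correlation). Of 36 inflammatory genes, 33 differed upward and 0 downward, also over the list alone, and 25 and 2 with that scaling, with a relative median of 2.86 (camera adjusted p = 0.0016; adjusted p = 0.25 with an estimated correlation). Of 76 ribosomal protein genes, 3 differed upward and 70 downward, also over the list alone, and 0 and 76 with that scaling. Rpl41 was at −2.40, with a relative median of −2.18 (camera adjusted p = 2.1e-43; adjusted p = 0.022 with an estimated correlation). Of 76 oxidative phosphorylation subunits, 18 differed upward and 29 downward, 17 and 29 adjusted over the list alone and 0 and 64 with that scaling. Cox4i1 was at −2.08, with a relative median of −1.12 (camera adjusted p = 2.8e-08; adjusted p = 0.26 with an estimated correlation). Of 66 genes of ER translocation and ER-Golgi transport, 58 differed upward and 0 downward, also over the list alone, and 39 and 10 with that scaling. Creb3l1 differed by 7.97, with a relative median of 0.68 (camera adjusted p = 6e-04; adjusted p = 0.71 with an estimated correlation). Of 21 fatty acid synthesis genes, 19 differed upward and 1 downward, also over the list alone, and 13 and 4 with that scaling. The desaturase Scd2 differed by 4.39, with a relative median of 1.09 (camera adjusted p = 0.025; adjusted p = 0.66 with an estimated correlation). That call was lost without replicate 3 of labelled wildtype, EBSS (adjusted p = 0.064).

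Of 70 lysosomal genes, 31 differed upward and 26 downward, also over the list alone, but 12 and 45 with median-of-ratios scaling, with a relative median of −0.92 (camera adjusted p = 5.2e-05; adjusted p = 0.26 with an estimated correlation). Of 51 autophagy genes, 25 differed upward and 15 downward, also over the list alone, but 9 and 28 with that scaling, with a relative median of −0.73 (camera adjusted p = 0.0098; adjusted p = 0.66 with an estimated correlation). Of 56 mitotic genes, 48 differed upward and 2 downward, 49 and 2 adjusted over the list alone and 15 and 9 with that scaling. Their relative median was 0.26 (camera adjusted p = 0.048; adjusted p = 0.94 with an estimated correlation), and the call was lost with that scaling (adjusted p = 0.39) and without any one of 9 libraries. These were all except replicates 1 and 2 of wildtype, full medium and replicate 1 of labelled KO, EBSS, with adjusted p from 0.052 to 0.078. Of 6 macrophage markers, 1 differed upward and 4 downward, also over the list alone and with that scaling, with a relative median of −2.91 (camera adjusted p = 0.0031; adjusted p = 0.36 with an estimated correlation). Of 9 epithelial markers, 3 differed upward and 2 downward, 2 and 2 adjusted over the list alone and 0 and 3 with that scaling, with a relative median of −1.16 (camera adjusted p = 0.033; adjusted p = 0.26 with an estimated correlation). Median-of-ratios scaling ended the calls of the macrophage list (adjusted p = 0.18) and of the epithelial list (adjusted p = 0.36), the macrophage call was also lost with quantile normalization (adjusted p = 0.1), and the epithelial call with a pseudocount of 0.1 (adjusted p = 0.1) and without replicate 1 of labelled wildtype, EBSS (adjusted p = 0.052).

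Over all genes, 9710 (76.7%) passed limma's adjusted p of 0.05 for the interaction, 8123 upward and 1587 downward. The median difference was 1.06, and median-of-ratios scaling called 8449, 4296 upward and 4153 downward. At 2-fold or more, 6439 were upward and 942 downward. Camera passed 12 of 37 lists, and 1, the ribosomal proteins, with an estimated correlation. The sample titles number the replicates with the tag brep, which may stand for biological replicate. They do not say that replicates came from separate cultures, so every p here measures the spread between these libraries only. How much of that spread is technical is unknown.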

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

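Of the tests below, the positions of the EBSS libraries, the correlation over chromosomes, the chromosome 9 segments, the comparison of Rbbp5 with chromosome 9, and all 3 tests of the single EBSS library were chosen only after the results were seen, and 3 of them replaced or changed earlier tests (the reading of the correlation over chromosomes, Rbbp5 with chromosome 9, and the ATF4 targets).

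The libraries labelled KO, EBSS lie close to wildtype, full medium in expression. Those labelled wildtype, EBSS lean to KO cells over the genes that differed most in full medium. Over all tested genes, their correlations were only slightly higher with KO, full medium (0.861 to 0.902) than with wildtype, full medium (0.849 to 0.884). A scale was set over 583 genes at least 4-fold apart in full medium, with wildtype at 0 and KO at 1. On it the libraries labelled KO, EBSS lay at 0.10, 0.01 and 0.00 and those labelled wildtype, EBSS at 0.84, 0.85 and 0.88. Exchanged labels of the 2 EBSS groups are therefore a candidate explanation (highest position of labelled KO, EBSS 0.1). An exchange of genotypes alone would make the libraries labelled KO, EBSS starved wildtype cells. Replicates 2 and 3 of that group had only 47 and 35 of 9868 genes at least 2-fold from the mean of wildtype in full medium. The median of their ATF4 targets lay at 0.00 and −0.1 against it. An exchange alone leaves these values unexplained. The medians of 20 chromosomes reversed between full medium and EBSS (Pearson's r −0.94, permutation p = 1e-05, the smallest that 1e+05 permutations can give). On chromosomes 9, 14, X and 8, labelled KO, EBSS lay at 0.01, 0.00, −0.06 and 0.00 against wildtype in full medium. Labelled wildtype, EBSS lay at 0.01, 0.07, 0.03 and −0.08 there against KO in full medium, but at −0.21 on chromosome 12. Opposite responses under correct labels also allow a reversal, so the medians speak against them only if the shifts come from copy number, which was not measured. The rise of Rbbp5 in labelled KO, EBSS, by 1.40 with median-of-ratios scaling, speaks against opposite responses only if the exons left after the deletion did not rise. A deletion that failed in the labelled KO, EBSS cultures alone would leave labelled wildtype, EBSS like wildtype. The chromosome 9 genes of labelled wildtype, EBSS were at −0.43 relative to all genes (SE 0.04, from a bootstrap over genes). That speaks against a failed deletion only if the shift marks the culture and is not a response to EBSS, which was not tested. Scaling alone is argued against by positions of at least 0.63 in labelled wildtype, EBSS with median-of-ratios scaling and 0.56 with quantile normalization. What also stays open is that the 102 signature genes higher in KO put labelled wildtype, EBSS at only 0.40, 0.36 and 0.11 with median-of-ratios scaling, and that Rbbp5 there was above KO in full medium by 0.55 (SE 0.13, limma adjusted p = 0.0026) as deposited and by 1.33 (adjusted p = 2.4e-06) with that scaling.

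In full medium whole chromosomes differed between KO and wildtype, with the 543 genes of chromosome 9 that have a mean TPM of at least 5 at a median of −0.45 relative to all genes, those of chromosome 14 at −0.35, X at −0.30 and chromosome 8 at 0.40. GC content, transcript length and expression level are argued against as the whole cause, since chromosome 9 stayed at −0.42 (bootstrap SE 0.03) after their trends were removed. Cultures that differ in chromosome copy number may explain the shift: all 12 segments of 10 Mb with at least 20 genes on chromosome 9 lay below the median of all genes, from −0.61 to −0.23, but no DNA was analysed here. Loss of RBBP5 cannot be told apart from such a difference between cultures, because Rbbp5 and the chromosome 9 shift fell on the same side in 4 of 4 groups as deposited, the form of the test first used, and in 3 of 4 with median-of-ratios scaling. If copy number is the cause, part of the difference between KO and wildtype in full medium may not be an effect of RBBP5.

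Replicate 1 of labelled KO, EBSS stood apart from replicates 2 and 3, with 498 of 9868 genes at least 2-fold from the mean of wildtype in full medium, against 47 and 35. Mixing with another of the 12 libraries is argued against by Ddit3, at 2.92 times the highest of the other 11, and lower depth by 51 tested genes listed at 0, against 68 and 66 in replicates 2 and 3. Replicates 2 and 3 may not have had a starvation response: the median of the ATF4 targets was at 0.00 and −0.1 against wildtype in full medium (0.05 and −0.03 relative to all genes), and at 1.62 in replicate 1 (1.60); in labelled wildtype, EBSS it was at −0.22, −0.25 and −0.04 as deposited but at 0.72, 0.64 and 0.92 relative to all genes. An earlier test of the same explanation went the other way, since wildtype libraries in full medium had only 10 to 20 genes at least 2-fold from the mean of their 2 partners, but it set single libraries against the spread of replicates and was replaced. Beyond the labels, the medium of these 2 libraries is not given in the sources used here.

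The response to EBSS differed between the labelled genotypes for 9710 genes in limma's test of the interaction, and for 255 of the 276 genes that the naming rule selects for an EBSS comparison; the share over all tested genes was 76.7%, and a rule that picks large EBSS changes favours such genes. By the same test of the difference, and by camera for lists, relative medians differed upward for ER-Golgi transport at 0.68, mitotic genes at 0.26, fatty acid synthesis at 1.09, matrix at 2.48, interferon-stimulated genes at 3.5 and inflammatory genes at 2.86. With an estimated correlation none of these 6 calls held (adjusted p = 0.71, 0.94, 0.66, 0.66, 0.66 and 0.25), the mitotic call was lost with median-of-ratios scaling (adjusted p = 0.39) and without any one of 9 libraries (adjusted p from 0.052 to 0.078), and that of fatty acid synthesis without replicate 3 of labelled wildtype, EBSS (adjusted p = 0.064). They differed downward for autophagy at −0.73, lysosome at −0.92, ribosomal proteins at −2.18, oxidative phosphorylation at −1.12, macrophage markers at −2.91 and epithelial markers at −1.16. With an estimated correlation ribosomal proteins passed (adjusted p = 0.022) and the other 5 did not (adjusted p = 0.66 for autophagy, 0.26 for lysosome, 0.26 for oxidative phosphorylation, 0.36 for macrophage and 0.26 for epithelial markers). The macrophage and epithelial calls were also lost with median-of-ratios scaling (adjusted p = 0.18 and 0.36), the macrophage call with quantile normalization (adjusted p = 0.1), and the epithelial call with a pseudocount of 0.1 (adjusted p = 0.1) and without replicate 1 of labelled wildtype, EBSS (adjusted p = 0.052). Single genes set apart by it were Rbbp5 at 2.52, H19 at 13.73, Crabp1 at 12.62, Igfbp3 at 12.23, Gjb2 at 9.72, Has2 at 9.71, Serpina3g at 9.48, Kap at 9.45 and Tuba8 at 9.14. With the 2 EBSS genotype labels exchanged these would be at 0.54, −0.38, 1.12, 0.00, 0.71, 1.68, 0.26, −0.66 and −1.21, in the same order, and with median-of-ratios scaling at 1.27, 0.02, 1.68, 0.42, 0.67, 1.99, 0.49, −0.69 and −0.79. Of Rbbp5 in that comparison, the adjusted p was 0.025 as deposited and 9.7e-05 with that scaling (limma). Apart from Rbbp5, these genes were picked for the largest interactions. They are low in both KO, full medium and labelled wildtype, EBSS. That choice favours small values with exchanged labels, so they do not tell which labels are right. On the negative side were Rpph1 at −6.9, Acta1 at −6.69, Rmrp at −6.41, Cyp2e1 at −6.38, Rn4.5s at −5.94, Snhg9 at −5.57 and Rnu3a at −5.42. With exchanged labels these would be at 6.31, −3.12, 5.68, 0.78, 4.44, −0.82 and 3.53, and with median-of-ratios scaling at 7.14, −2.35, 6.49, 1.56, 5.22, −0.01 and 4.29. That scaling ended the call of Snhg9 (adjusted p = 0.042 as deposited and 0.98 with it).

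Other divisions of the same libraries were counted for each comparison. The 6 libraries of a comparison make 10 splits into 3 and 3, too few for a share under 0.05, and in each of the 4 pairwise comparisons 1 split, the real one, gave as many genes. The real counts were 7078 for KO in full medium, 10182 for labelled KO in EBSS, 10260 for EBSS in labelled wildtype and 6861 for EBSS in labelled KO, and the highest of the other splits were 0, 0, 1 and 1 in limma at an adjusted p of 0.05. For the interaction, 1 of 100 shuffles of the genotype labels within each medium, the real one, gave as many genes (9710). Shuffles that mix groups far apart widen the spread within groups and so call fewer genes, which favours the real division. This rank therefore does not exclude chance, and it does not tell which EBSS labels are right. The highest other shuffle called 7292.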

How the results depend on the processing

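The 2 removals of pairs of libraries, the interaction with the EBSS labels exchanged and the comparisons of groups that differ in both factors were chosen after seeing the data; all other alternatives were planned. The cause of each change below was not tested, except where its construction is named. Counts of called genes stayed within 1.5 times of those reported in all planned settings for the 5 planned comparisons, except with a 2-fold minimum, which by construction leaves fewer genes: 2542 for KO in full medium, 6186 for labelled KO in EBSS, 6398 for EBSS in labelled wildtype and 2405 for EBSS in labelled KO. Leaving out each library in turn gave 5941 to 8607, 9780 to 10611, 9719 to 10648 and 5776 to 8401, and 9220 to 10370 for the interaction, each highest without replicate 3 of labelled wildtype, EBSS. Without that library and replicate 1 of labelled KO, EBSS the 5 counts were 9640, 10868, 11128, 9100 and 10838, and without replicates 2 and 3 of labelled KO, EBSS they were 7186, 9341, 10283, 5528 and 9193. The interaction needs all 12 libraries, so it has no fit on 6. With the EBSS genotype labels exchanged it called 7999 genes, and 5971 with median-of-ratios scaling. For KO in full medium, library weights gave 10366 genes and the fit on its 6 libraries 9679. Similar counts did not mean the same genes. In the order above, median-of-ratios scaling kept 5929 of 7078 calls, 6539 of 10182, 6836 of 10260, 5928 of 6861 and 6561 of 9710, whatever their direction. Quantile normalization kept 5727, 5994, 6324, 5779 and 6244 of them.

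With the replicate block the 5 counts were 6922, 10107, 10191, 6702 and 9626, and Rbbp5 was at −1.53, 0.99, −0.98, 1.54 and 2.52. The comparisons across both factors had 7 (labelled KO, EBSS against wildtype, full medium) and 9432 (labelled wildtype, EBSS against KO, full medium). The replicate numbers do not pair the libraries: 0 of 18 same-numbered pairs had deviations correlated above 0.1 (−0.07 to 0.08), and in 16 of 36 checks a library matched its own number best, a hint from the data and not the design. The block changed the call of 0 of 81 list results and of 3 of 145 gene results, all 3 of them in limma's comparison of labelled KO, EBSS with wildtype, full medium (Malat1, Wnt7a and Tfrc).

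That comparison, with 17 called genes, was the least stable. It gave 32 with no filter, 56 with quantile normalization, 11 with no trend, 9 with a 2-fold minimum, 249 with only the 6 libraries compared and 5331 with array weights. It gave 748 without replicate 3 of labelled wildtype, EBSS and replicate 1 of labelled KO, EBSS, and 1547 without replicates 2 and 3 of labelled KO, EBSS. The opposite comparison gave 5474 with a 2-fold minimum and 8745 to 9925 with each library left out in turn.

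Rbbp5 lost its difference between the EBSS groups with median-of-ratios scaling (0.07, adjusted p = 0.59) and quantile normalization (0.02, adjusted p = 0.9). It also lost its difference for EBSS in labelled wildtype, at −0.02 (adjusted p = 0.88) and at 0.05 with quantile normalization (adjusted p = 0.68). Over libraries left out, Rbbp5 ranged from −1.61 to −1.46 for KO in full medium, 0.85 to 1.08 for labelled KO in EBSS, −1.04 to −0.93 for EBSS in labelled wildtype, 1.41 to 1.64 for EBSS in labelled KO, and 2.39 to 2.61 for the interaction.

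Of 145 named gene results, 145 kept direction and call with a pseudocount of 0.1 and with quantile normalization, and 142 with median-of-ratios scaling. Of 81 list results, 80 did with a pseudocount of 0.1, 72 with median-of-ratios scaling, 73 with quantile normalization, 54 with fry and 33 with an estimated correlation. Fry does not compare a list with other genes, so its direction follows the shift of all TPM values. It turned DNA replication (−0.19) and fatty acid oxidation (−0.03) in KO, full medium, and autophagy (0.5) and lysosome (0.4) in labelled KO, EBSS. For EBSS in labelled wildtype it turned ATF4 targets (−0.17), autophagy (−0.48) and lysosome (−0.4), and for the interaction autophagy (0.33) and lysosome (0.14). Median-of-ratios scaling turned the proteasome list to −0.25 (adjusted p = 0.17) in labelled KO against labelled wildtype, EBSS, and to 0.25 (adjusted p = 0.27) for EBSS in labelled wildtype. Depth, which TPM does not keep, limits low genes to an unknown extent.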

Other observations

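The comparisons of groups that differ in both genotype and medium, and the genes named for them, were chosen after seeing the data. Labelled wildtype, EBSS against KO, full medium had more RNA for ribosomal proteins and immediate early genes, and less for proteasome, cholesterol and mitotic genes. Hes1, a target of Notch signalling, was at 532 ± 24 TPM in labelled wildtype, EBSS and 19.7 ± 1.38 TPM in KO, full medium (mean ± SD, n = 3 each; log2 change 4.69, limma adjusted p = 1.8e-10). Fos rose by 4.54, Egr1 by 4.48, the snoRNA host genes Zfas1 and Snhg12 by 4.60 and 4.63 and Cxcl1 by 4.93, while Ccn2 was at −4.63 and Cdh17 at −4.96. Of 76 ribosomal protein genes, 72 were higher and 0 lower, and 76 and 0 with median-of-ratios scaling, with a median of 1.6 relative to all genes (camera adjusted p = 4.9e-50; adjusted p = 0.014 with an estimated correlation). Of 30 immediate early genes, 17 were higher and 8 lower, 19 and 3 with that scaling, with a relative median of 1.61 (camera adjusted p = 1.1e-08; adjusted p = 0.19 with an estimated correlation). Of 40 proteasome subunits, 0 were higher and 39 lower, 5 and 19 with that scaling, with a relative median of −0.33 (camera adjusted p = 6.9e-05; adjusted p = 0.043 with an estimated correlation). Of 26 cholesterol genes, 0 were higher and 25 lower, 2 and 23 with that scaling, at −1.17 (camera adjusted p = 0.00066; adjusted p = 0.5 with an estimated correlation). Of 56 mitotic genes, 0 were higher and 52 lower, 0 and 53 adjusted over the list alone and 4 and 38 with that scaling, at −0.69 (camera adjusted p = 9.3e-05; adjusted p = 0.71 with an estimated correlation). Over all genes, 9499 passed limma's adjusted p of 0.05, 1467 higher and 8032 lower, with a median change of −0.73, and 8007 with that scaling, 3800 higher and 4207 lower.

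Labelled KO, EBSS against wildtype, full medium gave 17 genes at limma's adjusted p of 0.05, 11 higher and 6 lower, with 1382 at an unadjusted p under 0.05 and 14 genes with median-of-ratios scaling. Across genes, the change in this comparison rose with transcript GC content (Spearman's rho 0.38). The cause of that trend was not tested. The brain cytoplasmic RNA Bc1 was higher by 2.98 (adjusted p = 0.0068), Rpl37rt by 2.35 (adjusted p = 0.007) and Rpph1 by 1.64 (adjusted p = 0.0048). The microRNA Mir221 was at 7.74, 5.15 and 11.3 TPM in wildtype, full medium and listed at 0 in the other 9 libraries (adjusted p = 8.2e-05). It passes the filter on low values only through those 3 libraries, so it is not tested without any one of them. The transferrin receptor Tfrc was at −0.65 (adjusted p = 0.02), Wnt7a at −1.44 (adjusted p = 0.012) and Malat1 at −1.14 (adjusted p = 0.033). The count was 0 without replicate 1 or without replicate 3 of wildtype, full medium in limma (733 and 715 at an unadjusted p under 0.05). It was 5 without replicate 2 of that group, 10 and 8 without replicates 2 and 3 of labelled KO, EBSS, and 219 without replicate 3 of labelled wildtype, EBSS. Bc1, Rpl37rt and Rpph1 lost their calls without replicate 1 or 3 of wildtype, full medium (adjusted p = 0.059 and 0.063), and Wnt7a without any one of that group's 3 libraries (adjusted p = 0.087, 0.072 and 0.063). Tfrc lost its call without any one of those 3 (adjusted p = 0.18, 0.08 and 0.19), without replicate 3 of KO, full medium (adjusted p = 0.053) or replicate 2 or 3 of labelled KO, EBSS (adjusted p = 0.058 and 0.068), and with median-of-ratios scaling (adjusted p = 0.08). Malat1 lost its call with that scaling (adjusted p = 0.085) and without any one library except replicate 3 of labelled wildtype, EBSS, replicate 2 of KO, full medium and replicate 1 of labelled KO, EBSS (adjusted p from 0.053 to 0.24). Camera passed 11 of 37 lists, and 0 with an estimated correlation, and fry passed 1. The ATF4 targets had a relative median of 0.54 (camera adjusted p = 1.5e-08; adjusted p = 0.9 with an estimated correlation) and the ER folding list 0.38 (camera adjusted p = 2.2e-07; adjusted p = 0.9 with an estimated correlation). Replicate 1 alone carried both, with medians of 1.62 for ATF4 targets and 1.16 for ER folding, against 0.00 and −0.1, and 0.07 and 0.05, in replicates 2 and 3.

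Replicate 1 of labelled KO, EBSS had the highest ATF4 and ER values of its group, and its genes here were chosen after their values were seen. Herpud1, a factor of ER-associated degradation, was at 956 TPM there and at 87.1 and 59.1 TPM in replicates 2 and 3. The stress genes Trib3, Ddit3 and Chac1 were at 307, 1940 and 199 TPM, against 27.1 and 21, 249 and 160, and 30.4 and 23.1 TPM. Hspa5 was at 8020 TPM against 1550 and 1390, and Sdf2l1 at 526 against 80.8 and 64.1. By list, medians relative to wildtype, full medium were 1.62 for ATF4 targets, 1.16 for ER folding, 1.08 for tRNA synthetases and 0.53 for NRF2 targets in replicate 1. The contractile list was at −0.93, mitotic genes at −0.61 and immediate early genes at −0.56. Interferon-stimulated genes were at 0.5 in replicate 1 and at −0.23 and −0.3 in replicates 2 and 3.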
